A study of Mus musculus with 6 samples.

How the data were processed

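RNA was measured in non-beta cells sorted by FACS from mouse islets, 3 libraries labelled wild-type (WT) and 3 labelled as a knockout of the glucagon receptor (GcgR KO). Per the labels' protocols, mice received 0.2 µmol/kg of a fluorescent exendin-4 conjugate 2 hours before islet isolation, and islets were cultured in medium with 11 mM glucose, 10% FBS and 2 mM glutamine before dispersal and sorting. Total RNA was depleted of ribosomal RNA, made into libraries with a stranded kit and sequenced in 50-cycle single-end runs, per the labels' protocols. All 6 samples are labelled as male C57BL/6J mice. The labels do not say whether each library came from separate animals, so that p-values measure the spread between these libraries, which may be technical in part.

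The authors deposited a table of RPKM values (reads scaled to gene length and to a library size), with 1 column per library and 23420 gene rows. The submitters' processing notes name FastQC, cutadapt 1.3, TopHat2 2.0.10, DESeq 2.0 and the build mm10, without saying what each was used for. The counting tool, the gene annotation, the use of strand, and the library size and gene length behind each RPKM are not given in the sources used here. Antisense and overlapping genes, and genes with near-identical copies such as ribosomal protein genes, are therefore uncertain. In the deposited table, 27 symbols had been turned into dates and 2 symbols were repeats of an earlier one. No other column of values was present (0 unused). Each column name shows a genotype but no replicate number, so a column was matched to its group only. Libraries are named here by that genotype and by the first part of the column name (6th, 10th, 15th or 16th), whose meaning is not given in the sources used here. The 10th and the 16th each mark 1 library of each genotype, and were treated as possible batches.

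Low RPKM values fell on whole multiples of a step, from which the library size behind each column and the reads behind each value were computed. With a tolerance of 0.0001 reads, 17209 of the 17211 genes above 0 in a library came out whole in every library, and 13623 of 13625 genes above 0 in at least 4 libraries. With wrong library sizes, 41 of 1000 such genes did. The length that makes reads whole is fixed only up to a multiple, and the candidate nearest the annotated exon length was taken, so a gene's reads carry that uncertainty while their ratios between libraries do not. Recovered reads per library were 3235254, 1441385 and 2049147 in the WT-labelled libraries marked 10th, 6th and 16th, and 4404217, 1259585 and 2520107 in the KO-labelled libraries marked 10th, 15th and 16th. These totals were from 0.995 (WT-labelled 10th) to 1.85 (WT-labelled 6th) times the library size. A gene whose length was taken at a multiple counts too many reads, so the totals may be too high. In the WT-labelled 6th, 830869 recovered reads lay outside small RNA genes, against a library size of 777555. What that size counted is therefore not settled. In a gene of 2 kb, 1 read is worth between 0.12 and 0.643 RPKM. Reads without molecular identifiers are not independent molecules.

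Values were divided by median-of-ratios factors over the 9617 genes above 0 in all 6 libraries. The factor was 1.04 in every library, so the deposited values already carried that scaling. Genes with a mean of at least 0.5 scaled RPKM were kept (14040 genes) and tested on log2(scaled RPKM + 0.5) with limma 3.58.1 in R 4.3.3, with a mean trend in the prior variance and Benjamini-Hochberg adjustment. All tests were two-sided and the threshold was an adjusted p of 0.05. A fold change on this scale understates the change of low genes. Levels are printed as deposited RPKM, and mean ± SD is over 3 libraries. A second test followed the subtraction of the median log2 value of 17 alpha cell markers in each library. Levels of the targeted gene and means of gene lists per library were compared by exact permutation tests, which cannot give a p under 0.1 with 3 against 3.

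Before the data were examined, 32 lists of cell type markers and processes were fixed, with 736 members, of which 719 were matched to a row, with older symbols matched through RefSeq synonyms. No member of the list of mitochondrially encoded genes was matched and that list was not analysed here. The 28 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. For each list, the genes past the threshold were counted over all genes tested and adjusted over the list alone. The rule for named genes, also fixed then, was 13 genes whatever their values (among them Gcgr, Gcg, Slc38a5, Slc38a4, Slc7a2, Ins1, Ins2, Sst, Ppy, Pyy and Mki67, the others not being reported here), and up to 4 members of each list with the smallest p, or 2 where no member was called. The rule also took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 scaled RPKM, a symbol that is not of a predicted gene and no overlap between genotypes, and 10 rises and 5 falls relative to alpha markers by the same criteria. No gene was called in either test, so those parts of the rule named none. Any other gene is said to have been chosen after its values were seen. Gene positions are from GENCODE M21 on GRCm38 (mm10), which held 92.9% of the symbols.

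The test was checked on simulated reads for 3 against 3 libraries, drawn from the means and spread of these libraries. Over 13235 genes it called 48% of the genes changed 4-fold and 86% of those changed 16-fold, and 10 unchanged genes. With no gene changed it called 1 gene over 13282 genes. Over 13078 genes, limma's voom on simulated reads called 74% and 89% of the genes changed 4-fold and 16-fold, and 15 unchanged genes. Simulated genes took the median spread of genes at a like mean and were drawn independently. Changes were set only in genes above a floor of mean reads, and no library was given a spread of its own. These shares therefore do not give the power of the tests in these data.

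Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter and a filter at 2, values as deposited, quantile normalization, a total without the 50 highest genes, robust and array-weighted limma, each library left out, a 2-fold minimum, and other alpha marker shifts. Chosen after seeing the data were voom on the recovered reads (a mean of at least 5 reads), with and without quality weights and without the WT-labelled library marked 6th, the column mark or the Xist class (above 5 RPKM or not) as a term, leaving out small RNA genes, limma without a mean trend, and a shift by the mean of the alpha markers. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.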

Results

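The data were RPKM values of 23420 genes in non-beta cells sorted from mouse islets, 3 WT-labelled and 3 KO-labelled libraries. Non-beta cells of the islet are mainly glucagon-secreting alpha cells, with delta and PP cells and non-endocrine cells. Recovered reads ranged from 1259585 to 4404217 per library, totals that may be too high where a gene's length was taken at a multiple. Genes above 0 numbered 14647, 10923 and 14617 in the WT-labelled libraries marked 10th, 6th and 16th, and 14653, 14187 and 14082 in the KO-labelled libraries marked 10th, 15th and 16th. The WT-labelled library marked 6th stood apart. Its correlations with the other libraries on the log2 scale, across genes, were 0.637 to 0.719, and the first principal component, with 45.8% of the variance, set it against the rest.

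**Figure D1:**
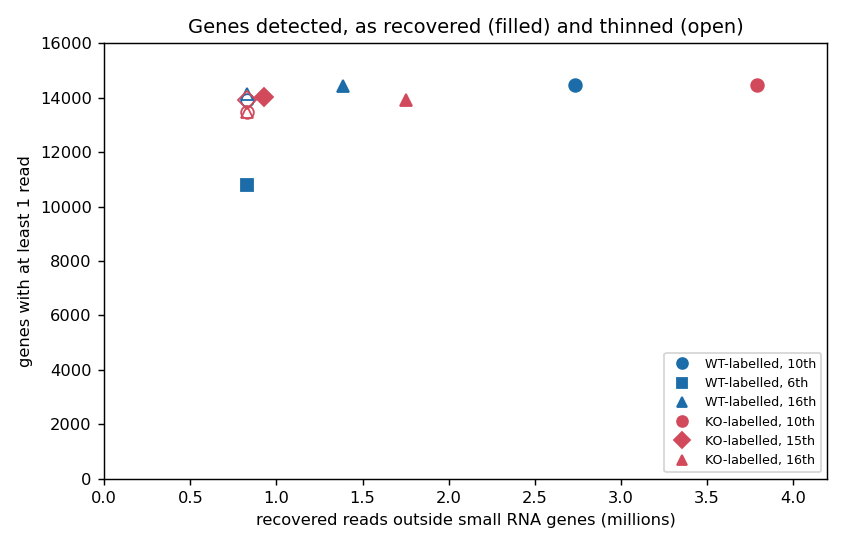
Genes with at least 1 read against recovered reads outside small RNA genes (in units of 1e6 reads), per library, as recovered (filled) and after thinning to 830869 reads (open). The WT-labelled library marked 6th detected 10785 genes, and the other 5 libraries thinned to its reads at least 13475.

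The targeted gene was examined first, since it checks the labels. Gcgr, the glucagon receptor (chromosome 11, 120530699 to 120538986, GRCm38), was listed at 2.23, 0 and 3.61 RPKM in the WT-labelled libraries marked 10th, 6th and 16th. In the KO-labelled libraries marked 10th, 15th and 16th it was at 9.31, 8.59 and 6.32 RPKM. The log2 difference, KO-labelled minus WT-labelled, was 2.23 ± 0.78 (SE, n = 3 and 3), which did not pass the test (limma adjusted p = 0.536). An exact permutation test of the RPKM gave p = 0.1, the smallest it can give. Within the marks that hold both genotypes, the log2 difference was 1.84 for the 10th and 0.73 for the 16th. The level in the KO-labelled libraries thus went against their label. It rested on few recovered reads: 14, 0 and 11 in the WT-labelled libraries and 75, 15 and 21 in the KO-labelled ones, in the same order. A value for the whole gene does not say which exons the reads came from, and the labels do not say which part was deleted, so reads outside a deleted part would check nothing. Libraries are called WT-labelled and KO-labelled for this reason, and every direction given here rests on those labels.

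The main comparison asked which transcripts of islet non-beta cells differ between the WT and GcgR KO labels. The amino acid transporter Slc38a5 (chromosome X, 8271133 to 8280179) was at 13.1 ± 12.1 RPKM in WT-labelled and 310 ± 24.8 RPKM in KO-labelled libraries (SD, n = 3), a ratio of means of 23.6. Its log2 difference was 4.86 ± 0.54 (SE), with no overlap between the genotypes, and the limma adjusted p was 0.0662. Vgf, which encodes a peptide precursor of secretory granules (chromosome 5, 137026392 to 137033351), was at 6.19 ± 3.10 and 52.3 ± 3.85 RPKM, with a log2 difference of 3.08 ± 0.38 and the same adjusted p of 0.0662. Gcg, the glucagon gene (chromosome 2, 62474530 to 62483650), was at 35772 ± 6983 and 96500 ± 3508 RPKM, a ratio of 2.70. No gene passed the threshold in limma: of 14040 genes tested, 0 were called, 1235 had an unadjusted p under 0.05 (753 higher and 482 lower in KO-labelled libraries) and 702 were expected by chance. The genotypes did not overlap for 15.8% of genes, where chance gives 10%.

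**Figure D2:**
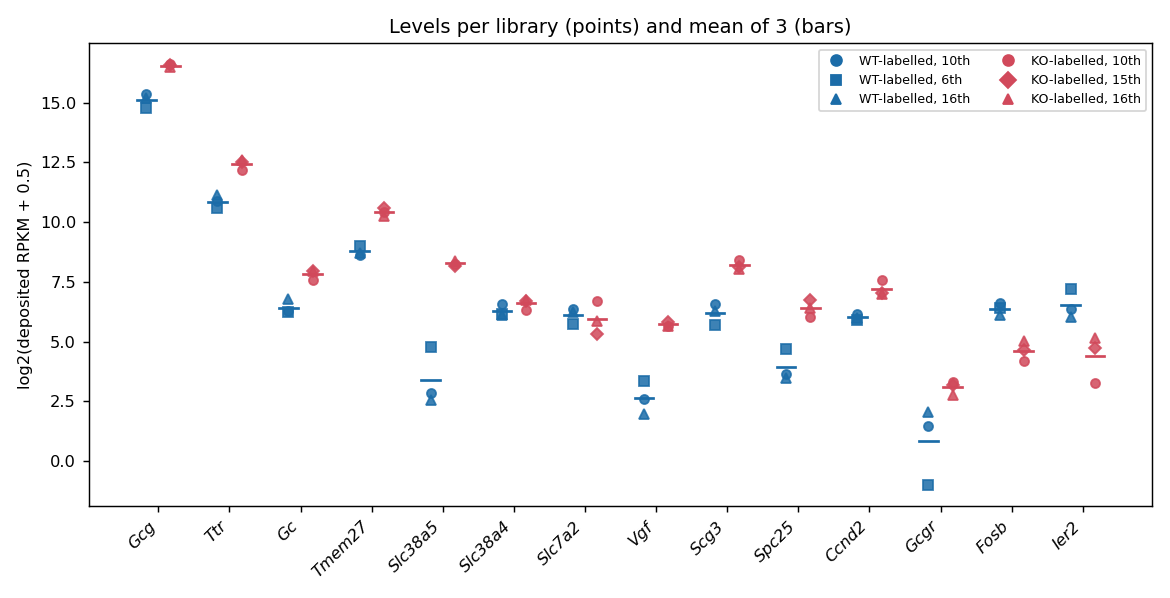
Levels of 14 named genes on a log2(RPKM + 0.5) axis, with 1 point per library and a bar at the mean of 3 libraries per genotype label. Slc38a5 sat between 286 and 335 RPKM in the KO-labelled libraries and between 5.46 and 27.1 RPKM in the WT-labelled ones, and Gcg did not overlap between the genotypes.

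The call on Slc38a5 depended on the libraries and on the settings, while its log2 difference stayed between 4.45 and 5.60 over the alternatives run (4.92 where the adjusted p was highest, 0.504). Without the WT-labelled library marked 6th, 11 genes were called, 8 higher and 3 lower, with Slc38a5 at 5.54 ± 0.28 (limma adjusted p = 0.00162, over a range of 0.000982 to 0.504 across alternatives). The 3 lower genes were the microRNA genes Mir133a-1, Mir350 and Mir496. Among the higher were Snord72, Mir30a and Mir1898, with 1 to 7 reads in each KO-labelled library and 0 in the WT-labelled ones. With its own weights and filter, voom on the recovered reads called 1 gene, Slc38a5 (adjusted p = 0.00748). On RPKM, Slc38a5 also passed with array weights (limma adjusted p = 0.000982) and with a total without the 50 highest genes (0.0114). For Gcg, the log2 difference was 1.45 ± 3.38 (SE) with limma's mean trend, which set a large prior spread for the few genes at the top of the range, and 1.45 ± 0.37 without a mean trend (adjusted p = 0.903 and 0.470). Within marks, Slc38a5 differed by 5.40 (10th) and 5.81 (16th) on the log2 scale, and Gcg by 1.25 and 1.31.

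The smallest adjusted p, 0.0662, was shared by 9 genes. Slc38a5, Vgf and Cd2 were named by the rule fixed beforehand, and the other 6 after their values were seen. Besides Slc38a5 and Vgf they were Dapl1, Cd2, 2310009A05Rik and the small RNA genes Snord72, Mir30a, Mir3960 and Mir1898. Dapl1 was at 1.61, 0 and 4.42 RPKM in the WT-labelled libraries marked 10th, 6th and 16th and at 119, 123 and 71.9 RPKM in the KO-labelled ones marked 10th, 15th and 16th. Cd2, a lymphocyte surface protein, was at 0, 0 and 0.553 RPKM against 10.3, 16.4 and 29.4 RPKM in the same order. The other 5 were listed at 0 in every WT-labelled library, and 4 of the 9 genes rested on fewer than 10 reads in every library.

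Among the genes fixed for naming, the amino acid transporters Slc38a4 and Slc7a2 had log2 differences of 0.32 ± 0.28 and -0.17 ± 0.40 (SE). Ins1 and Ins2, the insulin genes of beta cells, differed by -1.18 ± 1.59 and -1.24 ± 1.84. Somatostatin (Sst) differed by 0.66 ± 0.59, pancreatic polypeptide (Ppy) by -0.33 ± 1.16 and Pyy by 0.32 ± 0.71. Mki67, a proliferation marker, was at 0.502 ± 0.597 and 1.32 ± 1.34 RPKM (0.70 ± 0.83). None of these passed the test, with limma adjusted p between 0.713 (Slc38a4) and 0.937 (Ppy). With a library left out, the log2 difference ranged from 0.0081 to 0.54 for Pyy and 0.14 to 1.32 for Mki67.

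Gene lists were compared with other genes by camera. With the preset correlation, 10 of 28 lists passed, 5 higher and 5 lower in KO-labelled libraries. Other splits of the 6 libraries into 3 and 3 gave up to 11 lists, so that count does not set the genotypes apart. Estimated correlations in the 10 lists ran from 0.0085 (amino acid metabolism) to 0.81 (endothelial), where the preset was 0.01. Adjusted p from the preset can therefore be far too small. With an estimated correlation 0 passed (smallest adjusted p = 0.461), and with fry 0 passed (smallest adjusted p = 0.0857). fry's test for change in either direction passed for 10 lists, which were not the same 10. Amino acid transporters, hypoxia, cholesterol synthesis and mTORC1 were among them. The endothelial (fry adjusted p = 0.172), stellate (0.221), macrophage (0.564) and ribosomal protein (0.55) lists were not. Over all genes tested, 0 members of any list were called. List means per library were compared by exact permutation, whose smallest p is 0.1.

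**Figure D3:**
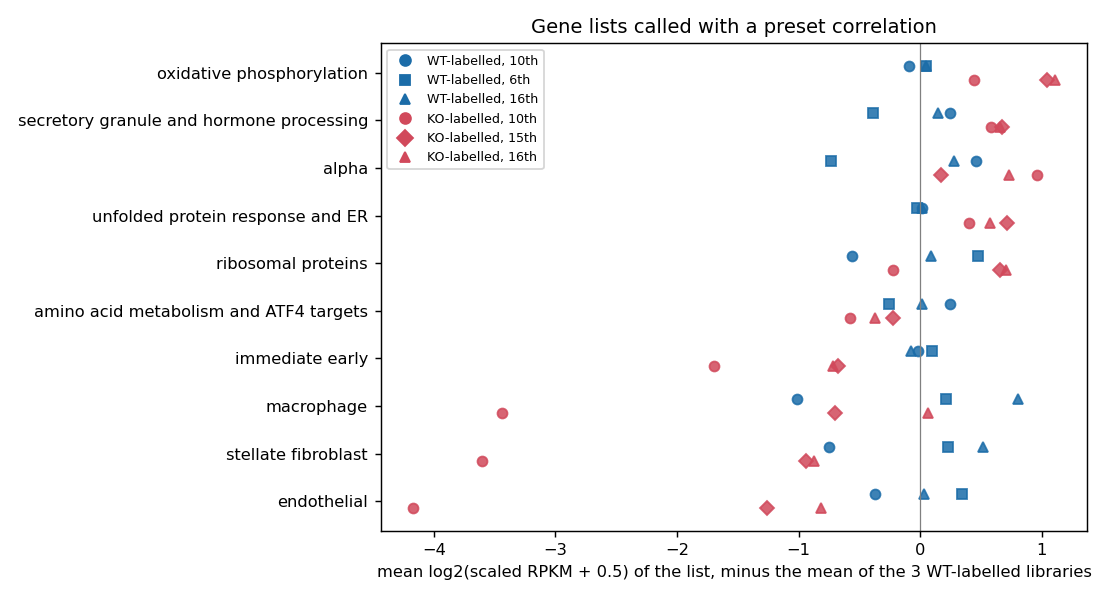
Mean log2 level of each of the 10 lists that passed camera with the preset correlation, per library, minus the mean of the 3 WT-labelled libraries. The KO-labelled library marked 10th lay lowest for the endothelial, stellate and macrophage lists, whose means there were 0.000591, -0.34 and -0.24 on the log2 scale before that subtraction.

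Genes of hormone secretion were among the higher lists. The list of secretory granule and hormone processing genes rose with the preset correlation (median log2 difference 0.69 over 30 genes, adjusted p = 0.000254), and its adjusted p was 0.461 with an estimated correlation. Of its members, 24 had a positive and 6 a negative fitted difference, and 5 were higher when adjusted over the list alone, among them Vgf and Scg3. Scg3, a granule protein, was at 74.8 ± 22.0 and 295 ± 37.9 RPKM (2.01 ± 0.32, SE). Over the alternatives run with the preset correlation, the mean difference of the list ranged from 0.34 to 0.77 (0.64 in the main test). The call was kept in 18 of 18 of these, but fry gave an adjusted p of 0.166. The list mean differed without overlap (exact permutation p = 0.1), by 0.34 within the 10th and 0.51 within the 16th. In the same libraries the mean of the alpha cell marker list differed by 0.62, and those of the endothelial, stellate and macrophage lists by -2.08, -1.80 and -1.36. Beside the same changes in cell type markers, genes of the unfolded protein response and endoplasmic reticulum rose with the preset correlation (median 0.54 over 29 genes, adjusted p = 6.83e-06), with an adjusted p of 0.461 with an estimated correlation and 0.0857 with fry. Adjusted over the list alone, 4 were higher and 0 lower. Manf, a secreted stress protein, went from 14.9 ± 6.37 to 49.9 ± 9.04 RPKM (1.79 ± 0.39) and Edem2, of endoplasmic reticulum degradation, from 10.3 ± 2.23 to 25.3 ± 1.72 RPKM (1.27 ± 0.30).

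Oxidative phosphorylation genes rose with the preset correlation (median 0.74 over 42 genes, adjusted p = 1.6e-10), and their adjusted p was 0.461 with an estimated correlation. Positive differences were fitted for 41 and a negative one for 1 of them, and 0 passed when adjusted over the list alone. Ndufv2 and Ndufa9, subunits of complex I, had log2 differences of 1.41 ± 0.34 and 1.45 ± 0.37 (SE). The list mean differed without overlap, by 0.53 within the 10th and 1.07 within the 16th, in the libraries where the alpha list mean differed by 0.62 and the endothelial, stellate and macrophage list means by -2.08, -1.80 and -1.36. Ribosomal protein genes also rose with the preset correlation (median 0.32 over 58 genes, adjusted p = 0.00482), but not with an estimated one (adjusted p = 0.879), and their list means overlapped (exact permutation p = 0.5). Rpl28 was at 68.0 ± 18.5 and 145 ± 33.1 RPKM (SD, n = 3), and Rpl34 was listed at 0 in the 3 WT-labelled libraries and at 1.20, 1.85 and 5.83 RPKM in the KO-labelled ones. The mean of 0.38 became 0.11 without the WT-labelled library marked 10th and the call was lost (adjusted p = 0.997), as it was without the WT-labelled 16th (mean 0.42, 0.0598) and without the KO-labelled 15th (mean 0.24, 0.141) or 16th (mean 0.22, 0.196). Without the WT-labelled 6th or the KO-labelled 10th the mean was 0.60 and 0.70, and the call was kept.

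The alpha cell marker list rose with the preset correlation (median 0.98 over 19 genes, adjusted p = 0.0410), with an adjusted p of 0.810 with an estimated correlation. Positive differences were fitted for 14 and negative ones for 5 of its members, and 2 were higher when adjusted over the list alone. These were Gc, a vitamin D binding protein, at 86.9 ± 18.9 and 228 ± 33.9 RPKM (1.40 ± 0.30, SE), and Tmem27, at 441 ± 59.8 and 1385 ± 149 RPKM (1.65 ± 0.40). Ttr, an abundant alpha cell transcript named after its values were seen, was at 1872 ± 349 and 5568 ± 854 RPKM (1.58 ± 0.71), without overlap. As for Gcg, that SE carries the prior spread limma set for high genes and is wider than the spread between libraries. List means overlapped (exact permutation p = 0.3). The call was kept in 11 of 18 alternatives run with the preset correlation. It was lost without the WT-labelled library marked 6th (mean 0.24 against 0.62, adjusted p = 0.293), the WT-labelled 16th (mean 0.76, 0.0828), or the KO-labelled 10th (mean 0.47, 0.314) or 16th (mean 0.57, 0.0574), and with a pseudocount of 0.1 (mean 0.69, 0.0507), the Xist class as a term (mean 0.53, 0.0703) or voom without the 6th (mean 0.33, 0.162).

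Immediate early genes, which respond within minutes to stimulation or to handling of cells, fell with the preset correlation (median -1.08 over 20 genes, adjusted p = 2.51e-10), and the adjusted p was 0.461 with an estimated correlation. Negative differences were fitted for 19 and a positive one for 1, and 7 were lower when adjusted over the list alone. Fosb went from 83.1 ± 14.1 to 24.6 ± 7.30 RPKM (-1.76 ± 0.31, SE) and Ier2 from 98.4 ± 44.4 to 23.4 ± 13.2 RPKM (-2.15 ± 0.53). The list mean differed without overlap, by -1.68 within the 10th and -0.64 within the 16th. It was lowest in the KO-labelled library marked 10th (3.05, against 4.07 and 4.03 in the KO-labelled 15th and 16th), where endothelial, stellate and macrophage markers were also lowest, and without that library the call was kept at a mean of -0.68 against -1.03. Genes of amino acid metabolism and ATF4 targets fell with the preset correlation (median -0.15, mean -0.39 over 29 genes, adjusted p = 0.0408) and had an adjusted p of 0.461 with an estimated correlation. Mthfd2, of mitochondrial folate metabolism, differed by -1.59 ± 0.50, and Bcat2, of branched-chain amino acid breakdown, by 1.98 ± 0.63. That call was lost without the WT-labelled (mean -0.26, adjusted p = 0.149) or the KO-labelled (mean -0.28, 0.164) library marked 10th, with no filter on low values (mean -0.31, 0.111) and with voom without the WT-labelled 6th (mean -0.81, 0.0732).

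Markers of non-endocrine cells made up the other lower lists. Endothelial markers fell with the preset correlation (median -2.05 over 14 genes, adjusted p = 7.57e-10), with an adjusted p of 0.522 with an estimated correlation, negative fitted differences for 14 of 14 and 1 member, Ptprb, lower when adjusted over the list alone. Ptprb went from 17.9 ± 0.425 to 5.51 ± 2.59 RPKM (-1.69 ± 0.39, SE) and Esam from 34.5 ± 8.97 to 8.57 ± 7.27 RPKM (-2.38 ± 0.72). Stellate and fibroblast markers fell (median -1.72 over 16 genes, adjusted p = 1.01e-07), with an adjusted p of 0.557 with an estimated correlation. Col1a1, a collagen chain, differed by -2.32 ± 0.77 and Rgs5, a pericyte marker, by -3.32 ± 1.25. Macrophage markers fell (median -1.08 over 19 genes, adjusted p = 0.000473), with an adjusted p of 0.799 with an estimated correlation. C1qb and Csf1r differed by -3.10 ± 1.20 and -2.38 ± 0.92. Without the KO-labelled library marked 10th, the macrophage call was lost (mean -0.30 against -1.36, adjusted p = 0.10), while the endothelial and stellate calls were kept at means of -1.02 against -2.08 and -0.89 against -1.80. Over the alternatives run, the means ranged from -3.80 to -1.02 (endothelial), -3.36 to -0.89 (stellate) and -3.21 to -0.30 (macrophage). Within marks, the endothelial list differed by -3.80 (10th) and -0.84 (16th), the stellate list by -2.85 and -1.39, and the macrophage list by -2.42 and -0.74.

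Other cell type lists did not pass camera with the preset correlation. Median log2 differences were -0.25 for delta, 0.18 for PP, -0.23 for beta, 0.56 for ductal, 0.28 for acinar and -0.36 for Schwann cell markers. Rbp4 and Rgs2 of the delta list differed by 1.11 ± 0.33 and -1.49 ± 0.53 (SE). Krt7 and Krt18 of the ductal list differed by 0.87 ± 0.35 and 0.69 ± 0.30. Acinar list means per library spread from 0.38 to 10.4 on the log2 scale among WT-labelled libraries, with Ctrb1 at 110, 1753 and 4.28 RPKM in those marked 10th, 6th and 16th. Without the WT-labelled library marked 6th the acinar list passed (mean 2.83, adjusted p = 1.96e-05), and without the WT-labelled 16th it passed in the other direction (mean -2.20). With the column mark as a term it also passed (mean 1.93, adjusted p = 0.0198), as it did with voom without the 6th (1.87), but the differences within marks had opposite signs, -1.80 (10th) and 5.66 (16th). The ductal list passed without the WT-labelled 6th (adjusted p = 0.0223, and 0.0121 with voom) or the KO-labelled 10th (0.0217), and the beta list without the WT-labelled 10th (mean -0.96, adjusted p = 0.0417). The 3 epsilon and 3 lymphocyte markers tested were too few for camera and had medians of 1.83 and -0.48, the latter with a mean of 1.14 that rests on Cd2. Of the erythroid markers 2 were tested.

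The remaining process lists did not pass camera with the preset correlation. Cell cycle genes had a median of 0.42, with 1 member, Spc25, higher when adjusted over the list alone. Spc25, a kinetochore protein, was at 10.8 to 25.2 RPKM in WT-labelled and 65.0 to 106 RPKM in KO-labelled libraries (2.45 ± 0.39, SE), and Ccnd2, cyclin D2, at 64.4 ± 6.79 and 150 ± 35.4 RPKM (1.19 ± 0.29). Spc25 lies beside G6pc2, on the opposite strand, on chromosome 2 (69193895 to 69206194 and 69211073 to 69227841). G6pc2 differed by 1.35 ± 0.92 (SE) and overlapped between the genotypes. Whether their levels are linked was not tested. Amino acid transporters had a median of -0.13 and a mean of 0.02, and camera's direction was down. Among them Slc38a5 was higher when adjusted over the list alone, while Slc7a5 differed by -1.25 ± 0.38. Medians were 0.28 for cell cycle inhibitors, 0.51 for cholesterol synthesis, 0.20 for glucagon and incretin receptor signalling, 0.26 for glycolysis, 0.04 for hypoxia, -0.10 for the interferon response, 0.10 for ion channels, 0.30 for mTORC1 and nutrient sensing, -0.12 for replication-dependent histones and 0.30 for alpha cell transcription factors. The interferon response list passed without the KO-labelled library marked 15th (mean -1.10, adjusted p = 1.69e-05) and with the column mark as a term (mean -1.45, adjusted p = 4.51e-07), with differences of -1.41 within the 10th and -1.50 within the 16th, while its mean in the KO-labelled 15th was the highest of the 6 libraries (4.03, against 0.85 to 3.11). The column-mark difference takes nothing from the KO-labelled 15th, which has no WT-labelled library under its mark. Calls also appeared for cell cycle genes without the KO-labelled 16th (0.0387), and for histones without the WT-labelled 10th (0.00662) or the KO-labelled 16th (0.00954) and with quantile normalization (0.0385). camera's direction was down for hypoxia and ion channels, against their medians. Adjusted over the list alone, Higd1a was higher and Ndrg1 lower in the hypoxia list, Rragb and Lamtor2, of amino acid sensing by mTORC1, were higher, as were Mvd and Ifih1 in the cholesterol and interferon lists.

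The second comparison asked which genes differed relative to alpha cell markers, since the share of alpha cells in the sort can differ. After the shift, 0 of 14040 genes were called by limma, and 1920 had an unadjusted p under 0.05, 116 higher and 1804 lower. The median log2 difference of all genes was -0.65 after the shift, and Slc38a5 had an adjusted p of 0.347. Shifting by Gcg alone called 5218 genes, 21 higher and 5197 lower, whereas voom with quality weights on recovered reads called 717, 716 higher and 1 lower. The median of all genes was 0.65 where the markers' median was taken from recovered reads, so the direction of this shift depended on the scale.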

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

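Alternatives that used recovered reads, a column-mark or Xist term, no small RNA genes, no mean trend or the mean of the alpha markers were chosen only after seeing the data. No paired analysis was possible because the deposited columns carry no replicate numbers. The column-mark term compares the genotypes within the 10th and within the 16th, and is no full substitute. The other marks hold 1 library each and add nothing to the difference, which rests on 2 pairs of libraries. That fit leaves 1 degree of freedom for the spread. The column-mark term called 0 genes (smallest limma adjusted p = 0.42) and 12 lists, with the interferon response (-1.45, adjusted p = 4.51e-07) and acinar (1.93, 0.0198) lists added. From so few libraries, neither count can decide whether the genotypes differ. Using the values as deposited moved next to nothing, since all libraries had the same scaling factor, and is no independent check. The count of called genes, 0 in the main test, was 1 with a total without the 50 highest genes (1 higher), 23 with array weights (21 higher, 2 lower), and 1 with voom, 1 with voom and quality weights and 1 with voom without the WT-labelled library marked 6th (each 1 higher). Leaving out each library gave 0 to 11 called genes, 0 to 8 higher and 0 to 3 lower, with all 11 when the WT-labelled library marked 6th was left out. Of those 11, the 3 lower were microRNA genes, and 8 were also called with array weights, which gave that library a weight of 0.232. Relative to alpha markers, the count of 0 became 2 with voom (2 higher), 717 with voom and quality weights (716 higher, 1 lower), 1 with voom without the 6th (1 higher), 5218 with the shift by Gcg alone (21 higher, 5197 lower) and 0 to 4 with a library left out (4 without the WT-labelled 6th, 2 without the WT-labelled 10th and 2 without the WT-labelled 16th). The cause was not tested. Gcgr stayed higher in KO-labelled libraries and uncalled, at 1.32 to 2.83 with a library left out and 1.28 to 3.06 over all alternatives. The count of lists, 10, was 0 with an estimated correlation, which asks the same question as the preset one, 0 with fry, which does not compare lists with other genes, 12 with the column-mark term and 8 to 11 with a library left out. The alpha list lost its call with a pseudocount of 0.1 (adjusted p = 0.0507), the Xist term (0.0703) and voom without the 6th (0.162), and the amino acid metabolism list with no filter (0.111) and voom without the 6th (0.0732). Weighted, robust and no-trend settings do not enter the list tests. The depth limits low genes most, since in a gene of 2 kb 1 read is worth 0.643 RPKM in the WT-labelled library marked 6th.

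Among lists, signs turned only for those not called in the main test. No gene was called there, so the same could not be asked of genes. The cause of the turns was not tested. Among named genes, log2 differences turned for Ppy with quantile normalization (0.029), Sst with the column-mark term (-0.045) and Ins2 with the Xist term (0.021). With a library left out they ranged from -0.52 to 0.15 for Slc7a2, -2.87 to 0.24 for Ins1, -3.32 to 0.26 for Ins2, -0.96 to 0.12 for Ppy, -1.08 to 3.16 for Ctrb1 and -1.52 to 3.54 for Reg1. List means turned as follows. With a pseudocount of 0.1, Schwann (0.037). With a pseudocount of 1, amino acid transporters (-0.0051). With no filter, ion channels (-0.0049) and PP (-0.15). With a filter at 2, amino acid transporters (-0.067) and hypoxia (-0.021). With quantile normalization, amino acid transporters (-0.10), hypoxia (-0.052) and ion channels (-0.080). With voom, beta (0.10) and ductal (-0.010). With voom without the 6th, amino acid transporters (-0.11), beta (0.45), cell cycle inhibitors (-0.18), glucagon and incretin signalling (-0.15), hypoxia (-0.012) and ion channels (-0.22). With the column-mark term, amino acid transporters (-0.12), cell cycle inhibitors (-0.15), glucagon and incretin signalling (-0.062), hypoxia (-0.0097), ion channels (-0.10), PP (-0.012) and histones (0.012). With the Xist term, amino acid transporters (-0.033), beta (0.13), ion channels (-0.046) and histones (0.021). With a library left out, means ranged from -2.20 (without the WT-labelled 16th) to 2.83 (without the WT-labelled 6th) for acinar, each past the threshold, -0.14 to 0.10 for amino acid transporters, -0.96 to 0.24 for beta, -0.052 to 0.68 for cell cycle inhibitors, -0.14 to 0.69 for ductal, -0.10 to 0.45 for glucagon and incretin signalling, -0.043 to 0.14 for hypoxia, -1.10 to 0.51 for the interferon response, -0.17 to 0.14 for ion channels, -0.056 to 0.26 for PP and -0.66 to 0.15 for Schwann. The other named genes and lists kept their sign under the alternatives run.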

Other observations

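The tests on Xist, on the share of cell types, on genes with few reads and on other splits were chosen only after the results were seen, and those on thinned reads before. Metallothioneins, named after their values were seen, were lower in KO-labelled libraries without overlap. Mt1 was at 166 ± 68.9 and 19.9 ± 17.0 RPKM (SD, n = 3; log2 difference -3.52 ± 0.84, SE) and Mt2 at 74.2 ± 37.3 and 10.4 ± 10.2 RPKM (-3.13 ± 0.74), with limma adjusted p of 0.466 and 0.452. Chga, a granule protein, was at 1110 ± 87.9 and 2978 ± 718 RPKM (1.39 ± 0.56, limma adjusted p = 0.545), without overlap. Its SE also carries the prior spread limma set for high genes.

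The WT-labelled library marked 6th detected fewer genes than the others, 10785 outside small RNA genes. Fewer reads are argued against as the whole cause, since the other 5 libraries thinned to its 830869 reads still detected at least 13475 genes (20 draws). Genes recovered at a multiple of their reads outlast thinning more often. Before any thinning, the KO-labelled 15th detected 14019 genes at 927044 reads. Reads taken up by acinar transcripts, 7.67% of the reads of the 6th, are argued against likewise, with at least 13383 genes in the others at the reads left. Reads that are copies of few molecules stay open: 8.01% of the genes of the 6th had 1 to 3 reads, against 14.2% to 17.5% in the other libraries after thinning. The 6th itself was not thinned. A gene recovered at a multiple lacks some low counts there, while thinning creates them, so these shares cannot decide. A biological difference of that sample was not tested.

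Xist, expressed from the inactive X chromosome of females, was at 33.5, 0.144 and 0.141 RPKM in the WT-labelled libraries marked 10th, 6th and 16th and at 45.7, 54.8 and 0.356 RPKM in the KO-labelled ones marked 10th, 15th and 16th, all labelled male. The KO-labelled 15th had 0 reads of Ddx3y, Uty, Kdm5d and Eif2s3y, as female animals alone may give. In both libraries marked 10th, female animals alone are argued against by these Y genes, whose lower level was 55.7% of the mean of the 3 low-Xist libraries, and stray reads by Xist at 61.1% or more of the level in the 15th. A pool of both sexes there stays open and was not tested. Xist was above 5 RPKM in 1 WT-labelled and 2 KO-labelled libraries, and with the Xist class as a term 0 genes were called.

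Endothelial, stellate and macrophage markers were lower in KO-labelled libraries by a mean of -1.75 on the log2 scale (exact permutation p = 0.2), and by -0.75 ± 0.42 (SE, p = 0.4) without the KO-labelled 10th. Other non-alpha lists exceeded that mean by 1.83 ± 0.88 (PP), 1.94 ± 0.66 (ductal), 1.42 ± 1.19 (delta), 1.48 ± 0.79 (beta), 2.18 ± 3.09 (acinar) and 1.62 ± 1.19 (Schwann), of which PP and ductal lay past 2 SE. Whether every non-alpha cell type fell equally could not be decided, since the endothelial, stellate and macrophage lists were taken up because they had fallen. The mean of the delta, PP, beta, ductal, acinar and Schwann lists exceeded the endothelial and stellate lists by 2.08 ± 0.87 and 1.80 ± 0.85 (exact permutation p = 0.1 each). Without the KO-labelled 10th the excess was 1.32 ± 0.60 and 1.19 ± 0.65 (exact permutation p = 0.2 each), the latter under 2 SE. Over the macrophage list it was 1.35, under 2 SE (exact permutation p = 0.4). Without the KO-labelled library marked 10th, the endothelial and stellate means still differed by -1.04 ± 0.31 and -0.90 ± 0.39 (SE, exact permutation p = 0.2 each). In each list, both remaining KO-labelled libraries lay below every WT-labelled one, so lower values were not confined to the KO-labelled 10th. With 2 libraries against 3, a fall without that library cannot be told from the spread. For the macrophage list (-0.32 ± 0.66) the KO-labelled 10th alone stays open. The most abundant members of the endothelial, stellate and macrophage lists, Plvap, Sparc and Cd74, went from means of 94.1, 83.2 and 175 RPKM to 27.0, 24.7 and 58.4 RPKM. How far the sort kept or removed such cells was not tested, and an effect of the genotype stays open, untested.

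Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The genotype split called 0 genes and the highest other split 1, and a count of 0 is reached by any split. At an unadjusted p under 0.05 the genotype split had 1235 genes and the highest other 1056. Relative to alpha markers, the calls were 0 and 5, and the genes at an unadjusted p under 0.05 were 1920 and 1751. The split with 5 sets the 3 libraries with Xist against the rest. For lists, the genotype split gave 10 and the highest other 11, with 3 of 10 splits as large. The splits that keep the libraries of the 10th together and those of the 16th together gave 6 and 9 lists. With voom on recovered reads, the genotype split called 1 gene and the highest other 0, with 1 of 10 as large.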
